A study of Caenorhabditis elegans with 2 samples.

How the data were processed

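The data were peak lists from chromatin immunoprecipitation and sequencing of a fusion of NHR-129 with enhanced green fluorescent protein in whole L2 larvae of Caenorhabditis elegans, from 2 biological replicates of 1 group. Per the labels the library fragments were 150 to 350 bp long, the antibody is recorded under the name of the receptor, and the animals were of both sexes. The aligner, the peak caller, their versions, the reproducibility threshold and the read depths are not given in the sources used here. Depth therefore could not be set beside any value, and intervals on shares cover counting error only.

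Per the descriptions deposited with the samples, the authors made a relaxed list of peaks and background for each replicate from its own alignment and a control, and another from the pooled alignments and a control. They then selected a thresholded list by the irreproducible discovery rate from the pooled list and both replicate lists. The lists were deposited in ce11 and, separately, in ce10. The ce11 lists were used for all results, and the ce10 lists only as an alternative for values that need no annotation. The signal value per peak was set by the authors' caller on a scale that is not given, and it differs between the pooled and the replicate lists. Signals were compared on the log2 scale between the replicate lists and between X and autosomes, and otherwise used to order peaks. The deposited −log10 q-value was at its highest for all 6626 thresholded peaks (4.15), so it could not order them, and no p-value was given per peak. The thresholded list was the same as the 6626 pooled calls of highest signal. Most peaks had 1 width, 370 bp in 5059 of the thresholded peaks, and the median signal was 122. Merging overlapping intervals left 6450 peaks. The position of each summit was taken from the offset the authors deposited. No calls lay outside the 6 nuclear chromosomes, and all lay within the chromosome lengths of the WBcel235 reference, the same assembly as ce11. The sequence and gene models came from that reference (Ensembl release 115). Coordinates are 1-based.

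Replicates were compared by overlap of at least 1 bp, taking the strongest overlapping call, with chance from 200 circular shifts along each chromosome. Summits were assigned to 1 class each in the order promoter window (1000 bp upstream to 100 bp downstream of a coding gene's start), 5' UTR, coding exon, 3' UTR, other exon, intron and intergenic. Shares were tested against 10000 circular shifts of all summits, which keep the clustering of peaks. A summit between divergent genes counted for both. Gene lists were tested against all other coding genes by Fisher's exact test, motifs by an exact McNemar test against flanks, and chromosomes by an exact binomial test, each with Benjamini-Hochberg adjustment and a threshold of 0.05. Lists were defined by gene name, non-coding classes by the biotype of the annotation, and the histone list holds every gene named his. All names were found for 9 of the 11 lists that use them. The heterochronic list was limited to coding genes and so lacked its 5 microRNAs, and the cilium list lacked ift-140. Intervals on shares are 95% Wilson intervals, and those on odds ratios are exact conditional intervals.

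The lists, motifs, tests and the rule for naming genes were set before the data were examined. The rule took nhr-129 and its neighbours, the genes at the 20 strongest peaks, up to 4 members of each list with the strongest promoter peak, and the 5 peaks with the largest difference in rank between replicates. The alternatives set in advance were the ce10 lists, merged peaks, stricter overlap, windows of 500 and 2000 bp, only the stronger peaks, the calls of 1 replicate alone, other backgrounds for location and gene lists, and other windows and flanks for motifs. Shuffling of summit sequence with dinucleotide counts kept was added after the data were seen.

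The functions were tested on simulated data. For the location test, a list of 6626 simulated peaks, some of them placed in promoter windows, gave a promoter share of 52.8%, planted and chance hits together. That share was counted on the same map of classes that defined it, so its return was fixed in advance. Of 40 lists placed at random 0 passed the threshold, but their peaks were independent, unlike the clustered real ones. For the gene lists, over the coding and non-coding genes of the annotation, 100 of 100 lists given an odds ratio of 4 were called, and 11 of 540 unchanged ones. The changed lists were the same 5 in each simulation, of 81 to 322 genes, and each gene was drawn independently. Recovery in shorter lists was not measured, nor were false calls where neighbouring genes share a summit. For the motifs, an E-box planted in about 10% of the windows of 6626 random positions was recovered as an excess of 9.81%, with 0 of 15 other motifs called. For the overlap, 2000 simulated peaks of which 70% were shared gave 70.4%. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. Control libraries and read-level signal were not used here.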

Results

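Chromatin recovered with a tagged form of the nuclear hormone receptor NHR-129 was profiled in Caenorhabditis elegans at the second larval stage (L2) by chromatin immunoprecipitation and sequencing. The worms belonged to strain OP339, which carries an integrated transgene encoding NHR-129 fused to enhanced green fluorescent protein, and whole animals of both sexes were pooled. There was 1 group of 2 biological replicates, so no condition was compared with another. The questions open to these data were how well the replicates agreed, where the peaks lay, and which genes and sequences they marked. With no untagged strain in the design, peaks that do not depend on NHR-129 could not be told apart. The list thresholded on reproducibility held 6626 peaks in the ce11 assembly. The relaxed lists for the pooled reads, replicate 1 and replicate 2 each held 30000 calls. Read depths are not given in the sources used here. The signal value of each peak is the authors' own score, on a scale that is not given.

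The nhr-129 gene itself (WBGene00003719, chromosome V, 13329186 to 13331019, minus strand) carried no peak. Neither of its neighbours, the chemoreceptor gene str-37 and the receptor gene nhr-168, had a peak in its promoter. The nearest thresholded peak, at position 13358030 to 13358155, had its summit 27099 bp away, with signal rank 2425. No call fell within 20 kb of the gene in the pooled list or in either replicate's relaxed list. Each of these lists ended at 30000 calls, so weaker calls, if any, would not be seen. A region of that size would hold 12.5 pooled calls at the genome-wide density. The strain carries additional copies of nhr-129 in its transgene, and the library of control DNA against which peaks were called was not analysed here.

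The replicates shared most of their strongest calls. Of the 6626 thresholded peaks, 6616 overlapped a call of replicate 1 and 6603 overlapped a call of replicate 2. Both replicates had a call at 6593 peaks, or 99.5% (95% Wilson interval 99.3 to 99.6%), where shifting the replicate lists along the chromosomes gave 3.81% on average over 200 shifts. With summits required to lie within 100 bp the share was 96.3%. The 6626 strongest calls of replicate 1 overlapped those of replicate 2 in 5486 cases, or 82.8%, against 4.49% for shifted lists. Across the 6593 peaks the replicate signals were correlated with a Spearman rho of 0.82 and a Pearson r of 0.87 on the log2 scale (permutation test, p = 1e-05, the smallest that 100000 permutations can give). Peaks are not independent replicates. The list had been thresholded on reproducibility and held the 6626 strongest pooled calls. It is therefore a selected set, though the replicates did not agree on every peak in it. Among pooled calls below the threshold rho was 0.43 over the 12598 calls that overlapped a call of each replicate. Pooled signals there ran only from 15.6 to at most 63.4, against 63.4 to 6467 above the threshold. A narrower range can by itself lower rho. Replicate 1 signals exceeded those of replicate 2 by a median of 0.31 on the log2 scale, with a standard deviation across peaks of 0.49.

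**Figure D1:**
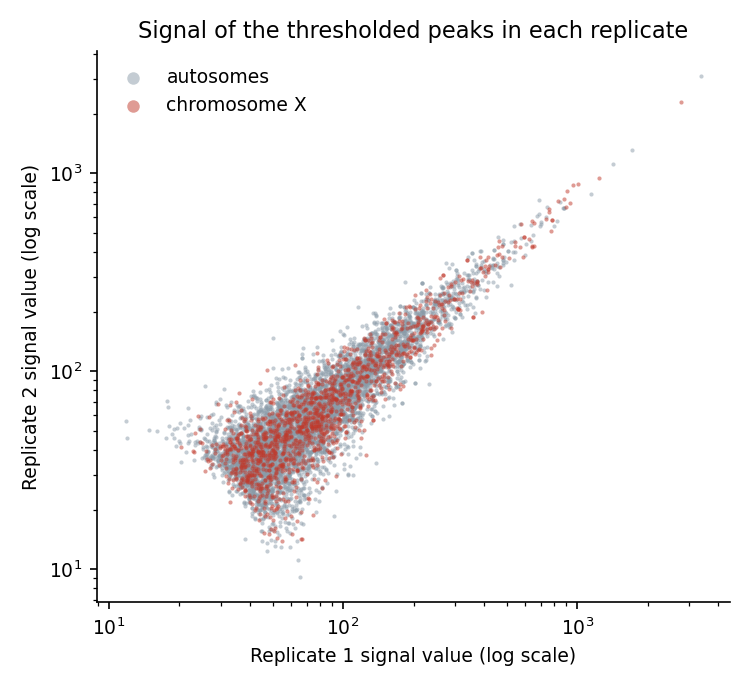
Signal value of each of the 6593 thresholded peaks called in both replicates, with replicate 1 on the horizontal and replicate 2 on the vertical axis (both log scales) and peaks on X in red. The points follow one diagonal, with a Spearman rho of 0.82, and spread most at low signal.

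The largest differences in rank between replicates were at peaks of low pooled signal. Rank favours such peaks, since weak calls lie close together in signal (quartiles of 12.1 and 32.6 in the replicate 1 list). The cause of the differences was not tested. The largest difference was at a peak in an intron of the globin gene glb-11 (chromosome III, 3991387 to 3991756), which ranked 3509 in replicate 1 and 29262 in replicate 2. The next 4 were a peak upstream of the collagen gene col-132, an intergenic peak 3615 bp from F54D1.6, and the promoter peaks of zhit-1 and of the divergent pair brc-2 and T07E3.3. All 5 had pooled signals of 63.9 to 76.5, near the lowest of the list, 63.4. The median difference in rank was 704.

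The strongest peaks ranked high in both replicates and were frequent on X. The highest signal, 6467, belonged to a peak in an intron of zip-2, a gene for a bZIP transcription factor (chromosome III, 833612 to 834150), which ranked 1 in each replicate. The next was 387 bp upstream of eef-1A.2, a gene for a translation elongation factor (X, 7823020 to 7823515), with a signal of 5056. Promoter peaks followed at Y58A7A.3 and at F44E7.5, where the summit also lay 260 bp upstream of the microRNA gene mir-253. The bZIP genes zip-3 (an intronic peak on II, rank 6) and cebp-1 (a promoter peak on X, rank 8) were also among the 10 strongest. The Pumilio-type gene puf-9 (rank 10), the F-box gene fbxc-19 (rank 14), the pair C49G7.10 and irg-2 (rank 16), nspc-17 (rank 17) and dld-1, which encodes dihydrolipoamide dehydrogenase (rank 18), also had a summit in the promoter. At rank 15 the promoter summit of F17C11.26 lay 69 bp upstream of a small nucleolar RNA gene. Of the 20 strongest peaks, 10 were in a promoter window, 5 were intergenic, 4 were intronic and 1 was in a coding exon of the polyketide synthase gene pks-1, 15210 bp from the nearest start, that of C41A3.2. The intergenic 5 had as nearest starts those of K02D3.1, W02H3.3, M163.11, F22H10.2 and F55G7.5, at distances of 1397 to 6026 bp, and all were on X. The remaining intronic peaks were in mom-1, nearest to the start of cest-16, and in Y62E10A.13. In all, 11 of the 20 were on X, and none of the 20 ranked lower than 30 in replicate 1 or 20 in replicate 2.

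Peaks concentrated just upstream of genes. Of the 6626 summits, 2956, or 44.6% (95% Wilson interval 43.4 to 45.8%), lay in the window from 1000 bp upstream to 100 bp downstream of the start of a protein-coding gene. Peaks shifted along the chromosomes gave 19.5% on average and at most 23.8% (permutation by 10000 circular shifts, two-sided p = 0.0002, the smallest the shifts can give). Upstream of the nearest start lay 65.8% of summits, against 41.7% of shifted ones. Coding exons held 2.78% of summits, 0.136 times the shifted mean of 20.5%, and 3' UTRs held 0.664%, 0.274 times. Introns were also below the shifted mean, at 23.4% against 31.4%, whereas 5' UTRs were above it, at 1.61% against 0.980%. Each of the differences in coding exons, introns and UTRs had an adjusted permutation p of 0.00028. Intergenic sequence beyond the window held 26.8%, close to the shifted 25.2% (adjusted permutation p = 0.021). Many annotated starts in this species may be trans-splice sites downstream of the site where transcription begins, and operons are not marked in the annotation used.

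**Figure D2:**
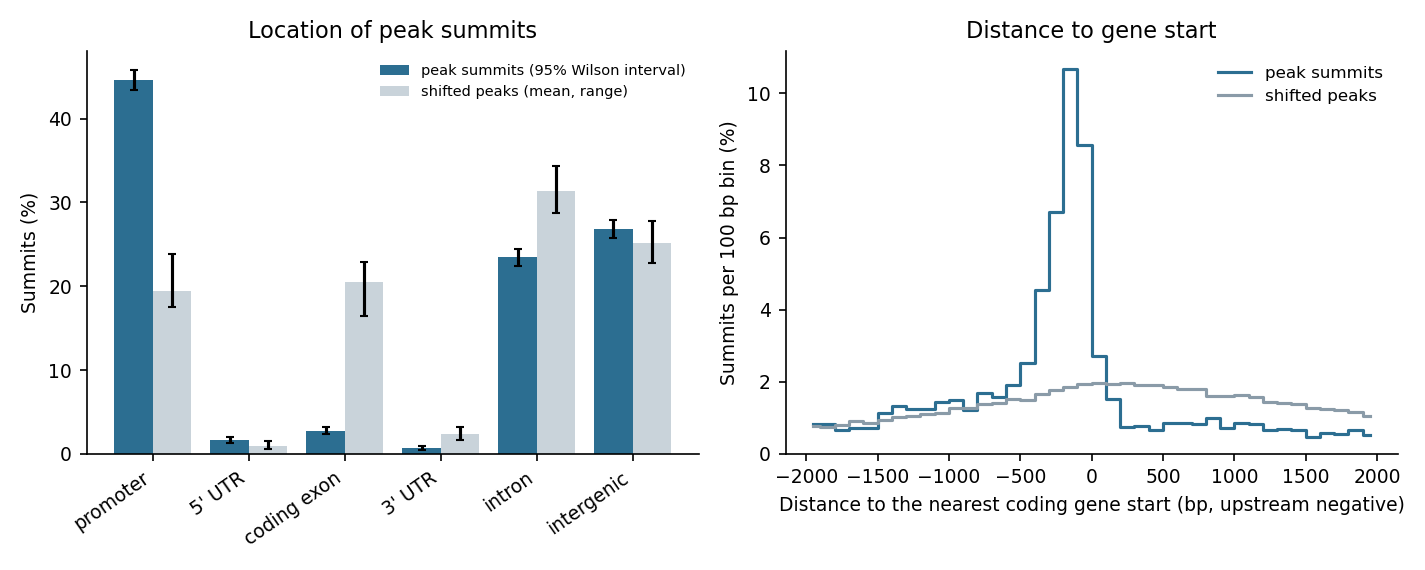
Left, share of the 6626 peak summits in each class of sequence (dark bars, 95% Wilson intervals) beside the mean and range of 10000 circular shifts (pale bars). Right, share of summits per 100 bp bin by distance to the nearest coding gene start. Promoters held 44.6% of summits against 19.5% of shifted ones, and the summits pile up just upstream of the start.

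Promoter location went with peak strength. In the strongest 20% of peaks (1326 peaks, signal 230 to 6467) 50.9% of summits lay in a promoter window, against 37.1% in the weakest 20%. The odds ratio was 1.76 (95% interval 1.50 to 2.06, Fisher's exact test, two-sided p = 9.93e-13). Coding exons went the other way, from 0.302% in the strongest group to 6.49% in the weakest, a trend that was not tested.

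Chromosome X carried more peaks than its length gives, and V fewer. X held 1402 peaks, or 21.2% (95% Wilson interval 20.2 to 22.2%), on 17.7% of the nuclear genome (exact binomial test, two-sided, adjusted p = 1.08e-12 over 6 chromosomes). Chromosome V held 15.8% on 20.9% of the length (adjusted binomial p = 2.44e-25), or 49.9 peaks per Mb against 79.1 on X. Chromosome III was above its length share, at 15.5% against 13.7% (adjusted binomial p = 8.10e-05), as was chromosome I, at 16.1% and 70.7 peaks per Mb (adjusted p = 0.0253). Chromosomes II and IV did not pass the test. The excess on X is set against length and not against genes. Of the coding genes on X, 19.6% had a summit in the promoter window, close to the 18.2% of all coding genes. That difference was not tested. On the autosomes, whose middle regions hold more conserved and highly expressed genes, the middle of 3 equal spans of each chromosome held 2382 of 5224 peaks, or 45.6% (exact binomial test, two-sided p = 3.39e-75). On X the middle span held 34.5% of peaks (exact binomial p = 0.350). These binomial tests treat peaks as independent, which neighbouring peaks are not.

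**Figure D3:**
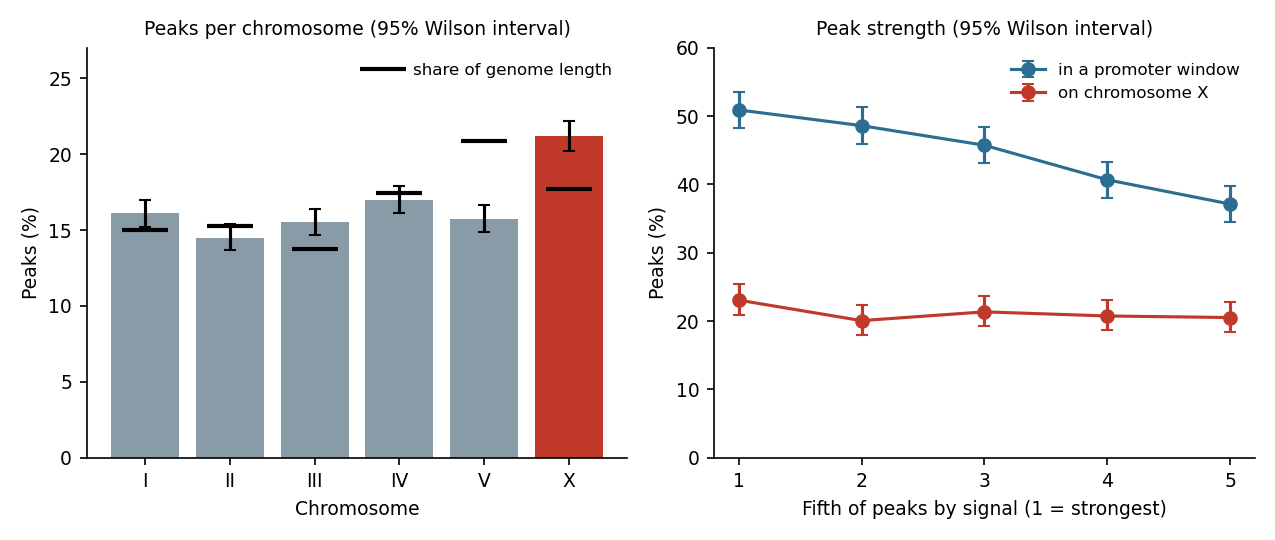
Left, share of the 6626 peaks on each chromosome (bars, 95% Wilson intervals) with the chromosome's share of the genome length (black marks). Right, share of peaks in a promoter window (blue) and on X (red) in each of 5 equal groups of peaks by signal, 1 being the strongest. X lies above its length share in every group, and the promoter share goes from 50.9% to 37.1%.

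A peak summit lay in the promoter window of 3640 of 19973 protein-coding genes, or 18.2%. The strongest calls of replicate 1 alone gave 3587 genes and those of replicate 2 alone gave 3557, of which 3136 were shared. Of 32 gene lists fixed before the data were examined, 16 differed from the other coding genes, 8 with more promoter peaks and 8 with fewer. The test was Fisher's exact test, two-sided, Benjamini-Hochberg adjusted over the 32 lists. It treats genes as independent, but neighbouring genes can share a summit, so its p-values may overstate the evidence. Rotating the calls along the gene order of each chromosome kept every call on a coding list. There the adjusted rotation p ranged from 0.00065, for chemoreceptors among others, to 0.0304 for insulin-like genes. Non-coding lists were not rotated.

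Ribosomal protein and proteasome genes were marked most, and chaperone genes were also above other genes. Cytosolic ribosomal protein genes had a promoter peak in 72 of 81 cases, or 88.9% (95% Wilson interval 80.2 to 94.0%, odds ratio 36.6, adjusted Fisher p = 1.19e-42), with the strongest at rpl-12 (signal 1309), rpl-3 (1226), rpl-35 (1111) and rps-13 (1032). Proteasome subunit genes followed with 26 of 33 (odds ratio 16.8, adjusted Fisher p = 2.84e-13), led by rpn-3 (signal 411) and pas-4 (338), then rpt-2 and pbs-3. Heat shock protein and chaperone genes had 28 of 59 (odds ratio 4.08, adjusted Fisher p = 7.78e-07). The strongest of these were hsp-60, for the mitochondrial chaperonin (signal 1077), hsp-3, for an endoplasmic reticulum chaperone of the BiP type (653), hsp-1 (505) and dnj-14 (436). The peak of rpn-3 also lay in the promoter window of hsp-110, so it counted in both lists. The call on proteasome genes was lost when only the 1000 strongest peaks were used (odds ratio 2.69).

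Respiratory chain, vacuolar ATPase and body wall muscle genes were also marked more than other genes. The mitochondrial respiratory chain had promoter peaks at 25 of 39 genes (odds ratio 8.06, adjusted Fisher p = 1.28e-09), among them cox-5B (signal 719), sdha-1 (646), cox-5A (584) and atp-1 (443). The vacuolar ATPase, the proton pump of acidic organelles, had them at 10 of 20 subunit genes (odds ratio 4.50, adjusted Fisher p = 0.00282), with vha-8 (732) and vha-15 (367) the highest. Body wall muscle markers had them at 20 of 30 genes (odds ratio 9.02, adjusted Fisher p = 2.27e-08). These included unc-112, for the kindlin of muscle attachments (357), unc-60, for cofilin (276), unc-89, for an obscurin-like sarcomere protein (193), and unc-98 (166). The muscle call was lost among the 1000 strongest peaks (odds ratio 1.92). No other tissue marker list passed the test in the higher direction with the 1000 bp window.

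Genes for tRNAs and small nucleolar RNAs also had summits in their windows more often than coding genes. A summit lay in the same window of 277 of 612 tRNA genes, or 45.3% (odds ratio 3.71, adjusted Fisher p = 4.25e-50), and of 153 of 346 small nucleolar RNA genes, or 44.2% (odds ratio 3.56, adjusted p = 3.13e-27). Many of these summits also lay in the promoter window of a coding gene. That held for every summit at 70 of the 153 small nucleolar RNA genes and 49 of the 277 tRNA genes, counts made after the data were seen. The small nucleolar RNA gene C16A3.11, for instance, shares its summit with rps-13. The strongest peaks at small nucleolar RNA genes, at F17C11.24 (signal 1549) and C06A1.9 (1250), ranked 15 and 30 of all peaks. The 4 strongest tRNA peaks were all on X, the highest with signal 860. Copies of tRNA genes are near-identical, so which copy a read came from is uncertain. Small nuclear RNA genes (17.8%), microRNA genes (48 of 261) and long non-coding RNA genes (35 of 194) did not pass the test. Strong single members were M163.13 (signal 1714) and the spliced leader gene sls-2.2 (926) among the first, mir-253 (2539) among the second and linc-84 (1317) among the third.

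Fewer promoter peaks were found at chemoreceptor, C-type lectin and F-box genes and at pseudogenes. Serpentine chemoreceptor genes, expressed mainly in sensory neurons, had them at 17 of 1309 genes, or 1.30% (odds ratio 0.0546, adjusted Fisher p = 4.18e-90), srw-7 (signal 695) and srd-35 (542) being the strongest. C-type lectin genes had 6 of 240 (odds ratio 0.114, adjusted Fisher p = 2.47e-13), with clec-126 the highest (285). F-box genes had 22 of 322 (odds ratio 0.325, adjusted Fisher p = 1.40e-08), although fbxc-19 (1552), fbxa-63 (771) and fbxa-37 (712) were among the 120 strongest peaks. Pseudogenes had 57 of 2128 (odds ratio 0.123, adjusted Fisher p = 8.78e-102). Reads shared between similar members of these families could affect calls at single members, which was not measured. The F-box call was lost among the 1000 strongest peaks, where the odds ratio was 0.505.

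Secreted peptide, cuticle and epidermal genes were also below other genes. FMRFamide-like and other neuropeptide genes had promoter peaks at 3 of 102 genes, flp-23, nlp-4 and nlp-24 (odds ratio 0.135, adjusted Fisher p = 1.10e-05), each with a signal below 100. Insulin-like peptide genes had 1 of 39, ins-39 (signal 836, odds ratio 0.118, adjusted Fisher p = 0.0127). Collagen genes, which encode cuticle components, had 13 of 156 (odds ratio 0.406, adjusted Fisher p = 0.00191), led by col-38 (365), whose peak is also in the promoter window of rpl-5, and col-2 (259). Epidermis and seam cell markers had 1 of 40, the RUNX-type gene rnt-1 (signal 130, odds ratio 0.115, adjusted Fisher p = 0.0127). Among the 1000 strongest peaks, which mark fewer genes, these 4 calls were lost, with odds ratios of 0.172 for collagens, 0 for neuropeptide genes, 0 for epidermal markers and 0.705 for insulin-like genes. The calls on insulin-like and epidermal genes were also lost among the 3313 strongest, at odds ratios of 0.221 and 0.215.

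Nuclear hormone receptor genes, the family of NHR-129 itself, did not differ detectably from other genes. A promoter peak was found at 55 of 269, or 20.4% (95% Wilson interval 16.1 to 25.7%, odds ratio 1.16 with a 95% interval of 0.841 to 1.56, adjusted Fisher p = 0.518). The strongest were nhr-58 (signal 609), nhr-57 (544), nhr-49, a receptor that regulates fat metabolism (508), and nhr-1 (507). Lipid metabolism genes had 8 of 42 (adjusted Fisher p = 0.971), with lbp-3 (804) and acs-2, for an acyl-CoA synthetase (628), the highest. Among detoxification families, cytochrome P450 genes had 14 of 74, led by cyp-33C8 (444), UDP-glucuronosyltransferase genes had 14 of 67, led by ugt-50 (1072), and glutathione S-transferase genes had 9 of 44, led by gst-27 (427). None of these families passed the test.

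Markers of several tissues and programmes gave no call in either direction. Intestine markers had promoter peaks at 2 of 24 genes, act-5 and erm-1, and pharynx markers at 1 of 22, pha-4. Without replicate 1 the pharynx list had none and passed the test (adjusted Fisher p = 0.0430, against 0.127 to 1 under the other alternatives). Germline markers had 4 of 34, led by cgh-1 (421), neuronal markers 7 of 30, led by ric-19 (267) and the synaptobrevin gene snb-1 (242), and cilium genes 6 of 45, led by daf-19 (181). Homeobox genes named ceh had 6 of 63, led by ceh-38 (801), and histone genes 12 of 72, led by his-37 (925). Heterochronic genes, which time larval development, had 4 of 13. These were lin-66 (792), lin-28 (178), lin-14 (174) and lin-46 (143). Of the microRNAs that this list lacked, and that its tests left out, lin-4, mir-48, mir-241 and mir-84 had no peak under their annotated names. For let-7 no value is given here. With the window extended to 2000 bp, neuronal (adjusted Fisher p = 0.0162) and heterochronic genes (adjusted p = 0.0331) passed the test. Across the other alternatives the adjusted p ranged from 0.336 to 0.878 and from 0.0883 to 0.622.

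**Figure D4:**
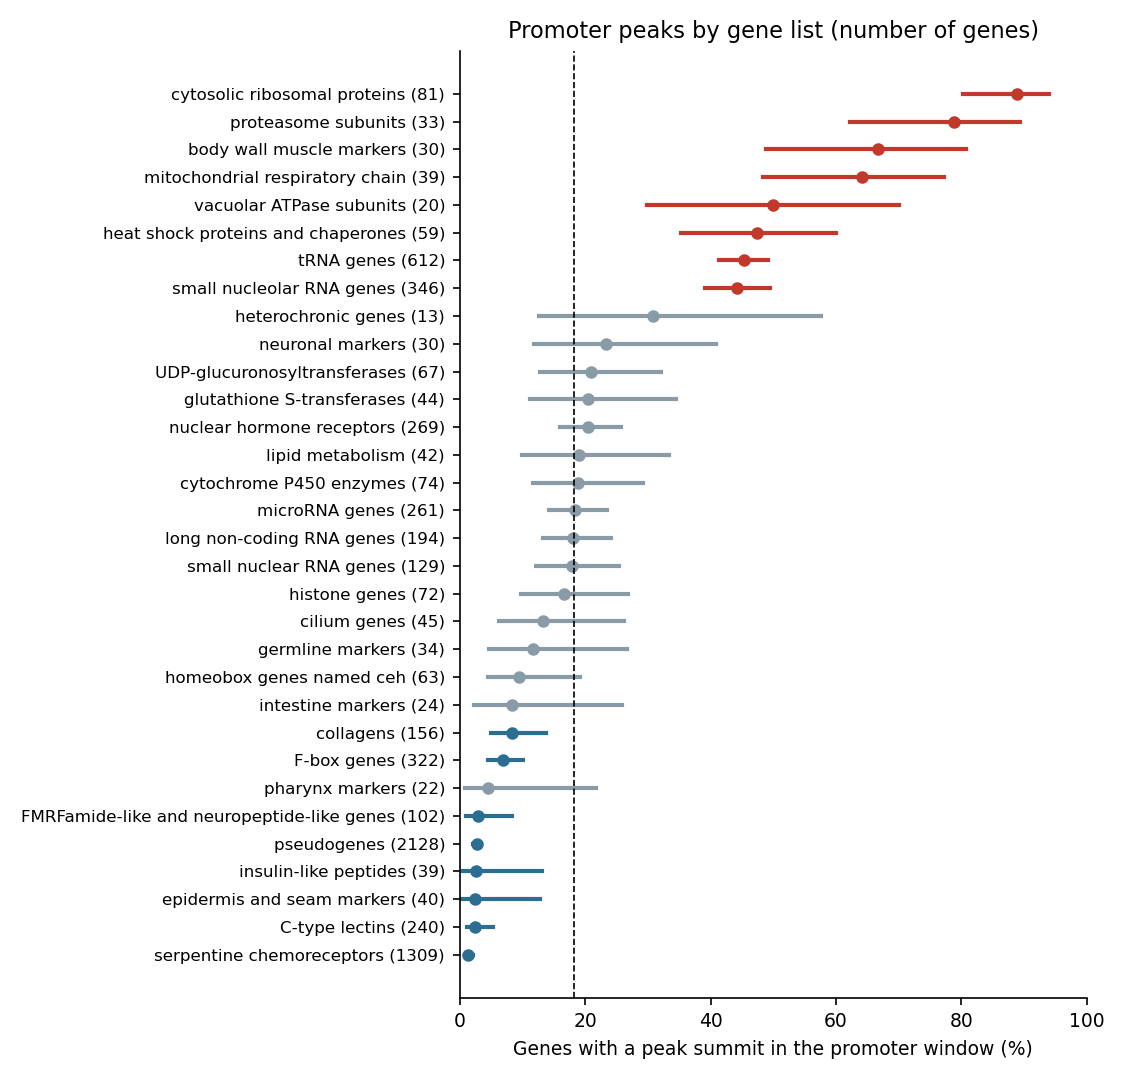
Share of genes in each of the 32 lists with a peak summit in the promoter window (points) with 95% Wilson intervals (lines) and the share over all coding genes, 18.2% (dashed line). Red marks lists with more and blue lists with fewer promoter peaks than other coding genes, and grey lists did not pass the test. Ribosomal protein genes stand highest at 88.9% and serpentine chemoreceptors lowest at 1.30%.

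The GAGA repeat had the largest ratio between summits and flanks of the motifs that differed, though most summits lacked it. Of 16 short motifs fixed before the data were examined, 10 differed between windows of 50 bp each side of the summit and windows 1000 bp away on the same peak (exact McNemar test, two-sided, Benjamini-Hochberg adjusted over the 16), 7 being more and 3 less frequent at summits. The repeat GAGAGAGA was found at 8.16% of summits and 1.34% of flanks, a ratio of 6.08 (adjusted exact p = 1.11e-82). In shuffled summit sequence, a background chosen after the data were seen, it was at 2.52%, which gives a ratio of 3.24. The E-box CACGTG was at 5.19% against 1.96% (ratio 2.65, adjusted exact p = 8.40e-24), CCGCCC at 4.47% against 2.07% (ratio 2.16, adjusted p = 1.73e-14), the E2F-type core TTSSCGC at 1.91 times the flank share of 3.67% (adjusted p = 4.62e-17) and CAGCTG at 3.98% against 2.48% (ratio 1.61, adjusted p = 2.16e-06). The FOXA-type site TRTTKRY differed little from flanks, at 29.1% against 26.9% (adjusted exact p = 0.00611), but more from shuffled sequence, at 19.8% (ratio 1.47). Against flanks it lost its call among the 3313 and the 1000 strongest peaks (ratios 1.08 and 1.01). The CAGCTG call was lost among the 1000 strongest (ratio 1.65, adjusted exact p = 0.0513).

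The nuclear receptor half-site AGGTCA was at 3.65% of summits and 2.69% of flanks (ratio 1.36, adjusted exact p = 0.00333). That difference did not pass the test without replicate 2 (adjusted exact p = 0.0537), among the 3313 strongest peaks (adjusted p = 0.399) or among the 1000 strongest (adjusted p = 1). Over the alternatives run its adjusted p ranged from 0.000114 to 1. Against shuffled summit sequence the half-site was at 3.65% against 3.89%. The variant AGTTCA was less frequent at summits, at 3.94% against 6.73% (adjusted exact p = 2.75e-12). The homeobox core TAATTA was also lower, at 1.19% against 4.62% (ratio 0.258, adjusted exact p = 2.80e-32) and against 1.86% in shuffled sequence (ratio 0.642). TATAAA was at 3.95% against 10.8% (adjusted exact p = 2.11e-51), but above shuffled sequence, at 3.95% against 2.99%. Summit windows were richer in G and C than flanks, at 45.2% against 36.1%. The GATA site WGATAR was alike at summits and flanks, at 21.5% against 21.4% (exact McNemar test, adjusted p = 0.882). It was below flanks among the 3313 strongest peaks (ratio 0.855, adjusted exact p = 0.00228), among the 1000 strongest (ratio 0.711, adjusted exact p = 0.000461) and without replicate 1 (ratio 0.899, adjusted exact p = 0.00279). Against shuffled summit sequence it was higher, at 21.5% against 15.8% (ratio 1.37, adjusted exact p = 4.31e-18). The extended site CTGATAA, the HNF4-type element CAAAGTCCA, the AP-1 and SKN-1 sites and the X-box did not pass the test against flanks either. Under alternatives against flanks, AP-1 passed it as higher with wider windows, nearer flanks and without replicate 1 (ratios 1.38, 1.53 and 1.46). SKN-1 passed it as lower with wider windows, in the 3313 and the 1000 strongest peaks and without replicate 1 (ratios 0.870, 0.725, 0.528 and 0.756), and CTGATAA as lower in the 1000 strongest (ratio 0.375).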

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

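A further 448 calls of the pooled relaxed list had the same highest −log10 q-value, 4.15, as the thresholded peaks but lay below the threshold, and the report did not examine them as a group of their own. Their median signal was 61.1, against a minimum of 63.4 in the thresholded list.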

How the results depend on the processing

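The test against shuffled summit sequence was added after the data were seen, and the other alternatives were planned. The higher share of promoter summits, of peaks on X and of promoter peaks among the strongest 20% of peaks kept its direction and its side of the threshold under every alternative run. The promoter share ranged from 36.0% with a 500 bp window to 56.9% with a 2000 bp window, the X share from 20.9% to 23.8% and the odds ratio from 1.48 to 2.13. The locus of nhr-129 had 0 peaks with either replicate alone and in the ce10 list. The replicate correlation stayed between 0.78 and 0.87. The share of peaks called in both replicates was 88.0% when 50% of both intervals had to overlap, 96.3% for summits within 100 bp, 82.2% when only as many calls of each replicate were used as there were peaks, 99.8% in the 3313 strongest and 99.9% in the strongest 1000 peaks. The share of the strongest calls shared by the replicates was 75.5% and 78.1% under the first 2 of these rules. A stricter rule tends to lower the share by construction, by an amount that also depends on how far the replicates differ. That was not tested. The 3313 and the 1000 strongest peaks are subsets and not stricter rules. The number of coding genes was 2121 from the 3313 strongest peaks and 718 from the strongest 1000, since fewer peaks were used. With the strongest 1000, 9 gene lists passed the test. The odds ratios of the lists changed there too, some of them towards 1, so the use of fewer peaks need not be the only reason. That was not tested. Of 250 gene list values under alternatives, 209 kept the outcome of the main test, whether a call or none. A call was lost in 9 and gained in 3, and 29 changed direction, every one of the last in a list without a call and none past the threshold. The odds ratios that changed direction were 0.978 for nuclear hormone receptors, 1.06, 1.02, 1.103 and 1.04 for histone genes, 0.954, 0.609, 0.366 and 0.884 for cytochrome P450 genes, 0.923, 0.982, 0.825 and 0.809 for UDP-glucuronosyltransferases, 0.841 for glutathione S-transferases, 0.984 and 0.923 for lipid metabolism, 0 for neuronal markers among the strongest 1000 peaks, 1.04 for cilium genes, 1.02, 1.02, 2.25, 1.05, 1.04 and 1.04 for small nuclear RNAs, 0.971 for microRNAs and 1.25, 1.77, 1.01 and 1.04 for long non-coding RNAs. Leaving out replicate 1 and replicate 2 gave opposite directions for cytochrome P450 genes (1.17 and 0.884), UDP-glucuronosyltransferases (0.809 and 1.1), lipid metabolism (0.923 and 1.25) and long non-coding RNAs (0.946 and 1.01). Of 110 motif values, 86 kept the outcome of the main test, whether a call or none, 6 lost a call, 9 gained one and 9 changed direction. The GATA site had ratios of 0.855, 0.711 and 0.899 in the 3313 strongest peaks, in the strongest 1000 and without replicate 1, each past the threshold. Against shuffled sequence the ratio was 0.938 for the nuclear receptor half-site, 2.07 for CTGATAA, 0.680 for AP-1, 1.40 for SKN-1 and 1.32 for TATAAA, and the last 4 passed the threshold. The GATA site was at 1.37 there and passed it in the higher direction. The HNF4-type element was at 0.875 with nearer flanks, on few matches. The cause of these changes was not tested. Ordering peaks by q-value was not possible because all had the same value. Depth is unknown, so its effect on the number of weak peaks could not be measured, and with 2 replicates a peak's signal has no useful error of its own.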

Other observations

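Of the tests below, that of the X share without motif peaks, those of gap length around nhr-129, the comparisons of motif shares between classes of peaks, for which the GAGA repeat and the E-box were picked, and that of 21U-RNA genes were chosen only after the results they follow had been seen. Genes named here that the report does not name were chosen after their values were seen.

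Long stretches without any pooled call lay mostly on chromosome IV and held many genes of 21U-RNAs, the piRNAs of this species. There were 14 gaps of at least 100 kb between neighbouring calls in the pooled relaxed list, 10 on chromosome IV, 3 on V and 1 on X, the longest 242 kb. They covered 2.32% of the nuclear genome but held 5005 of 15363 annotated 21U-RNA genes, or 32.6%. Circular shifts of those genes gave 9.77% on average but up to 34.4%, since the genes are clustered (permutation by 10000 shifts, two-sided p = 0.02). Each gap on V and X held at most 2 of these genes, so the pattern lay in the gaps on IV.

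Both the GAGA repeat and the E-box were less frequent in promoters and more frequent at the strongest peaks. The GAGA repeat was at 6.12% of promoter summits and 9.81% of others (Fisher's exact test, odds ratio 0.600, adjusted p = 1.38e-07 over 6 comparisons), and at 4.78% of summits on X against 9.07% on autosomes (odds ratio 0.503, adjusted p = 1.38e-07). In the strongest 20% of peaks it was more frequent than in the weakest (odds ratio 1.39, adjusted Fisher p = 0.0217). The E-box was at 4.13% of promoter summits and 6.05% of others (odds ratio 0.669, adjusted Fisher p = 0.000661), at 7.09% of summits in the strongest 20% of peaks and 3.32% in the weakest (odds ratio 2.22, adjusted p = 3.03e-05), and did not differ detectably between X and autosomes (odds ratio 1.20, 95% interval 0.916 to 1.55). No test compared the motifs with each other.

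X held 23.1% of the strongest 20% of peaks (95% Wilson interval 20.9 to 25.4%), above its 18.8% share of non-exonic sequence, which argues against more non-coding sequence on X as the whole cause. A candidate for part of this excess is signal at recruitment sites of the dosage compensation complex. Its 12 bp motif TCGCGCAGGGAG, with at most 1 mismatch, lay within 250 bp of the summit at 13 of 306 X peaks in that group, or 4.25%, and at 1 of 1020 autosomal ones, or 0.0980% (odds ratio 45.2, Fisher's exact test, p = 4.79e-08). Among the 100 strongest peaks it was at 10 of 41 on X against 1 of 59, and among the 20 strongest at 5 of 11 against 0 of 9. The 13 X peaks included those in mom-1 and pks-1. They also included 2 neighbouring peaks near the sex determination gene xol-1 (summits 8036406 and 8036613, ranks 22 and 1284), which the test counts as independent. With at most 2 mismatches the shares were 6.86% and 2.16% (odds ratio 3.34), and the motif with at most 1 mismatch has 32 matches on X and 37 on all autosomes, so some excess at X peaks would arise without recruitment sites. Leaving out peaks with the motif left 22.3% of that group on X (20.2 to 24.7%), so peaks with this motif are not the whole cause. A constant gain of signal on X stays open, since the log2 ratio of X to autosomal signal at matched peak density changed by 0.13 between strong and weak peaks (95% bootstrap interval -0.04 to 0.29). Signal of the immunoprecipitation that does not depend on NHR-129 could not be tested without an untagged strain, and the control libraries were not used here.

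A summit lay within 250 bp of 266 of 612 tRNA genes, or 43.5%, where 1000 shifts gave at most 7.03%. Neighbouring coding promoters are argued against, since tRNA genes with no coding start within 2000 bp had a summit in 42.1% of 273 cases (shifts at most 8.79%). Genes whose sequence occurs once in the genome had a summit in 39 of 140 cases, or 27.9% (shifts at most 10%), below the 43.5% of all tRNA genes. This argues against reads shared between exact copies as the whole cause. Genes with near-identical copies were not set apart, so reads shared with such copies stay open. An intact internal promoter of RNA polymerase III stays open, as genes with and without a match to the B box were alike in share (odds ratio 0.969, 95% interval 0.692 to 1.35, Fisher's exact test, p = 0.869). The criterion written beforehand took a p of at least 0.05 as evidence against this explanation, but was not applied, because a p above the threshold shows no absence and exact matches may miss working B boxes. Binding of NHR-129 itself was not tested against other explanations, since the design holds no second factor or untagged strain.

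The gap in calls around nhr-129 ran from 13300872 to 13358029 on chromosome V and held 16 coding genes, of which 4 encode serpentine chemoreceptors and 2 nuclear receptors. Reads that cannot be placed uniquely are argued against, since 98.1% of the 50-base words of the gap occur once in the genome. A chance gap stays open, because 44 gaps were at least this long and together hold 4.43% of the nuclear genome. Extra copies of the locus in the control may also account for a gap of 57.2 kb, but the ends of the transgenic fragment and the control's reads were not analysed here, and no biological explanation was tested.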
